A study of Rattus norvegicus with 21 samples.

How the data were processed

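Retinal RNA of Sprague Dawley rats was sequenced in 21 libraries, 3 for each of 7 groups, with libraries made by the VAHTS Universal V6 kit, per the labels' protocols. Groups were taken from the treatment label of each sample. The labels write LED where the design text of the series writes white light, and these names were matched by elimination, since blue and halogen light carry one name in both. No label gives the unit of the levels 200 and 1000, and none says what light the control animals received. An age of 8 months is filed under another field of the labels. The labels give 3 samples per group without saying that they came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

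The authors deposited a table of counts per gene, which held whole numbers for 19099 genes in 21 libraries, with gene symbols, GO terms and KEGG pathways. They also deposited a table of FPKM values for these genes. Each FPKM value equalled the count divided by the library's summed counts and by 1 whole-number length per gene, within a tolerance of 0.001 bases, for all 19099 genes, with a median length of 2840 bases. The FPKM table was therefore no independent measurement. R 3.2.0 is named per the submitters' processing notes; the aligner, the counting tool, the strand setting and the genome build are not given in the sources used here. Genes of multigene families, such as the RT1 genes of the major histocompatibility complex, the crystallins, the globins and the Gsta genes, could share reads between near-identical copies in the authors' counting, so their values are uncertain. Libraries held 30404774 to 35437448 counts, and a floor of 3 counts per library corresponded to 0.0847 to 0.0987 CPM (counts scaled to the same total in each library), a limit that covers counting error only.

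Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, TMM scaling and 1 mean per group fitted to all 21 libraries. The filter on low counts kept 16006 genes, with a minimum count of 10 in about 3 libraries and a minimum total of 15. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. All adjusted p-values of single genes come from this edgeR test unless another tool is named. The comparisons were each light group against control, the mean of the 6 light groups against control, level 1000 against 200 within each light source and over the 3 sources, the 3 pairs of sources, and the 3 differences between level effects, beside 1 test of any difference between the 7 groups. A log2 fold change is given ± its standard error, and a CPM mean ± its SD with n = 3. Where every library of a group had 0 counts, the fold is given as a bound against 3 counts per library, since the fitted value then depends on the prior count.

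Before the data were examined, the comparisons, the alternatives, the rule for naming genes and 39 gene lists were fixed, apart from the alternatives said to have been added. 36 lists had 3 or more tested members; the mitochondrially encoded genes matched 0 symbols of the table, the RNA quality list had 2 tested members and the Y-linked genes and Xist had 0. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation, and with fry. Camera compares a list with the other genes; fry tests whether a list's genes moved, on balance, one way, or in either direction in its mixed form, without comparing them with other genes. Members called are counted over all genes tested and again adjusted over the list alone. GO terms and KEGG pathways from the deposited annotation with 10 to 500 tested members were tested by Fisher's exact test, one-sided, against 14637 genes with a GO term and 6352 with a pathway.

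Named genes followed this rule: in the comparisons with control and the level comparisons within a source, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM, a symbol other than a provisional one and no overlap between the compared groups (no overlap criterion for all light); up to 4 called members of each list with the smallest adjusted p; where no gene was called, the 5 with the smallest p; and 12 fixed genes in every comparison with control. In the other comparisons the 5 called genes with the smallest adjusted p were named, and some genes that the rule picked are not reported here. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, only the compared groups in the fit, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), limma voom with quality weights, and leaving out each library in turn. After the data were examined 3 alternatives were added: scaling to the bipolar cell list, leaving out the 3 libraries with most lens RNA, and leaving out 3 libraries that lay between the other 2 of their group. Correlations of fold changes across genes between comparisons were set beside 10 simulations of unchanged groups against the same controls.

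The test was run on simulated counts with 200 genes changed by known folds. For Hal200 against control it recovered 46.3%, 76.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, and 4.3% of its calls were false. For Blue1000 against control, with the rod list also lowered 64-fold, the shares were 58.2%, 77.6% and 93.9%, 33 of 34 rod genes were recovered, and 2.0% of calls were false. With so few genes changed, these rates do not cover Blue1000 itself, where 54.3% of genes were called and direction depended on the scaling. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.93 to 116), so none was counted as a copy. A mixture of 2 would too, and values up to 10.8 all involved the 3 libraries between their group mates, so independence was not shown.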

Results

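Retinas of Sprague Dawley rats were compared by RNA sequencing after 6 months in different light. The title of the series concerns dental lighting and the blood-retinal barrier, the endothelial and pigment epithelial seal between blood and neural retina. The 7 groups of 3 libraries were a control group and groups under blue light (Blue), halogen light (Hal) and LED light, each at level 200 or 1000. Of 19099 genes 16006 were tested.

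Transcripts of rod photoreceptors, the cells of dim-light vision, separated the groups most. Genes of the rod list took 8.98 ± 0.352% in control (SD, n = 3) and 5.93 ± 1.47% in Hal200, as shares of all counts. They took 0.296 ± 0.141% in LED200, 0.185 ± 0.0145% in Hal1000, 0.179 ± 0.0126% in Blue200, 0.179 ± 0.0046% in LED1000 and 0.167 ± 0.0221% in Blue1000. The first principal component held 45.9% of the variance and set control and Hal200 apart from the other 15 libraries. The crystallin Cryaa, a lens transcript, reached 5137 CPM in Blue200 replicate 1, 3334 CPM in control replicate 3 and 2622 CPM in LED200 replicate 1. For nearly all genes that differed between their group mates, Blue1000 replicate 3, Hal1000 replicate 3 and LED1000 replicate 2 lay between the other 2 libraries of their group, and these 3 are called in-between libraries here.

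**Figure D1:**
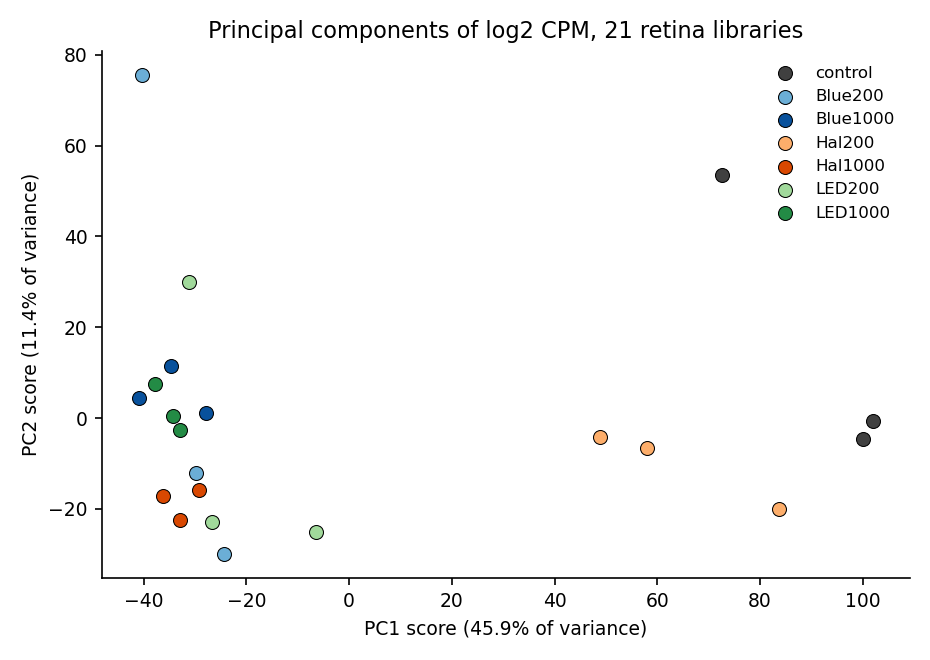
Each point is a library on the first and the second principal component of log2 CPM, with the share of variance on each axis and 1 colour per group (3 libraries each). Control libraries sit at 72.5 to 102 on the first component, Hal200 at 48.9 to 83.7 and the other light groups at -40.9 to -6.4.

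The mean of the 6 light groups against control asked which genes differed from control on average over the sources and levels. Rod photoreceptor genes were lower for 34 of 34, 34 adjusted over the list alone (camera adjusted p = 4.3e-23; 0.31 with estimated correlation). The median log2 fold change of this list was -5.14. Members were Gnat1 (-8.66 ± 0.57) and Pde6b (-7.90 ± 0.46), which encode the rod transducin alpha subunit and a rod phosphodiesterase. The rod transcription factors Nr2e3 (-8.21 ± 0.55) and Nrl (-7.86 ± 0.49) fell too, adjusted p from 1.6e-09 to 8.4e-09 over these 4 genes. Mgat4d, Clul1 and Btg4 fell from 10.7 ± 0.72, 207 ± 37.5 and 6.29 ± 2.33 CPM in control, adjusted p from 2.4e-11 to 9.3e-09. Their means were at most 0.0289, 2.53 and 0.0489 CPM in the light groups other than Hal200. The largest rises were RT1-CE16 (5.34 ± 1.4), RT1-Bb (5.29 ± 1.2) and Sbspon (4.14 ± 0.50), followed by Ca3 (3.98 ± 0.39), Slco1a5 (3.94 ± 0.68) and Thbs1 (3.92 ± 0.65). RT1-CE16 and RT1-Bb belong to the major histocompatibility complex, whose copies could share reads, and Thbs1 encodes thrombospondin. Sult1c3 and the nuclear receptor gene Hnf4a rose from 0.0246 ± 0.0426 and 0.0463 ± 0.0512 CPM in control to at most 2.14 and 2.55 CPM in a light group, adjusted p from 1.3e-07 to 0.010 over all 8. RT1-CE16, RT1-Bb and Slco1a5 lost their calls with voom quality weights (adjusted p from 0.069 to 0.37). Sult1c3 lost its call without Hal200 replicate 2 or with voom quality weights (adjusted p from 0.086 to 1). In all 9378 genes differed, 4711 higher and 4667 lower, 1919 of them by over 2-fold.

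Lists of the inner retina and of immune cells rose in the same comparison. Retinal ganglion cell genes were higher for 20 of 21 and lower for 1, 21 over the list alone (camera adjusted p = 6.7e-08; 0.31 with estimated correlation). Thy1 was at 0.75 ± 0.052 and Rbpms at 1.05 ± 0.083. Amacrine cell genes were higher for 16 of 19, 16 over the list alone (camera adjusted p = 1.6e-06; 0.036 with estimated correlation). Calb2 was at 0.81 ± 0.073, and of the 36 lists this one alone kept its call with an estimated correlation. Microglia and macrophage genes were higher for 21 of 26, 22 over the list alone (camera adjusted p = 1.5e-05; 0.60 with estimated correlation). Ptprc was at 2.05 ± 0.26 and Tmem119 at 1.51 ± 0.21. Complement genes were higher for 17 of 19, 17 over the list alone (camera adjusted p = 9.5e-05; 0.60 with estimated correlation). C4b was at 2.14 ± 0.25. Reactive gliosis genes were higher for 21 of 33 and lower for 3, 24 over the list alone (camera adjusted p = 3.0e-04; 0.60 with estimated correlation). A2m was at 1.44 ± 0.11 and Atf3, a stress-induced transcription factor, at -2.34 ± 0.24. Müller glia genes were higher for 14 of 20, 14 over the list alone (camera adjusted p = 5.2e-05; 0.54 with estimated correlation). Kcnj10, a potassium channel of these cells, was at 0.94 ± 0.061. Scaled to the bipolar list, the median of the Müller glia list turned from 0.51 to -0.11 in LED200 and stayed positive in the other groups. These 9 genes had adjusted p from 1.5e-10 to 4.2e-06.

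Pigment epithelium and vessel lists rose as well. Retinal pigment epithelium genes were higher for 20 of 27 and lower for 1, 21 over the list alone (camera adjusted p = 0.00026; 0.61 with estimated correlation). Ezr was at 1.28 ± 0.18, while Otx2, a transcription factor also made in photoreceptors and bipolar cells, was at -1.48 ± 0.085. Endothelial genes were higher for 21 of 24, 21 over the list alone (camera adjusted p = 0.00015; 0.60 with estimated correlation). Esam was at 0.85 ± 0.091 and Tie1 at 1.12 ± 0.18. Interferon response genes were higher for 17 of 34 and lower for 3, 22 over the list alone (camera adjusted p = 0.035; 0.85 with estimated correlation). Gbp2 was at 1.30 ± 0.28. Bipolar cell genes were higher for 14 of 19 and lower for 2, 16 over the list alone (camera adjusted p = 0.0022; 0.60 with estimated correlation). Vsx1 was at 0.84 ± 0.069 and Lrit3 at -2.05 ± 0.15. Antioxidant genes were higher for 18 of 31 and lower for 2, 20 over the list alone (camera adjusted p = 0.0014; 0.61 with estimated correlation). Hmox1, heme oxygenase, was at 1.62 ± 0.25, and scaled to the bipolar list the median of this list turned from 0.41 to -0.02. Genes of the unfolded protein and integrated stress response were lower for 16 of 34 and higher for 2, 18 over the list alone (camera adjusted p = 0.0094; 0.61 with estimated correlation). Atf4 was at -1.03 ± 0.081 and Ppp1r15a at -0.84 ± 0.089. These 10 genes had adjusted p from 2.4e-11 to 0.00069.

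Camera called none of the remaining 23 lists, with adjusted p from 0.051 to 0.99, although single members changed. Counted as higher, as lower and as called adjusted over the list alone, in this order, there were 17, 6 and 23 of 29 synapse genes, 4, 5 and 9 of 16 cone photoreceptor genes, 1, 1 and 2 of 10 horizontal cell genes and 6, 3 and 9 of 9 astrocyte genes. The counts were 7, 1 and 8 of 11 genes of oligodendrocytes and Schwann cells, 8, 9 and 17 of 23 circadian clock genes and 9, 9 and 18 of 28 immediate early genes. Hk2, a hexokinase of photoreceptors, was at -4.58 ± 0.18 and Arntl, a core clock gene, at -1.76 ± 0.074. Drd4, the dopamine receptor of photoreceptors, was at -2.70 ± 0.12, and Slc17a7, the vesicular glutamate transporter, at -1.34 ± 0.061. Counted in the same order (higher, lower, over the list alone), vessel and immune lists had 16, 5 and 21 of 27 angiogenic and permeability factors, 8, 5 and 13 of 28 tight and adherens junction genes, 7, 1 and 6 of 27 basement membrane and matrix genes and 3, 0 and 1 of 14 genes of pericytes and vascular smooth muscle. The counts were 7, 2 and 7 of 27 cytokine and adhesion genes, 10, 4 and 14 of 20 antigen presentation genes, 2, 1 and 3 of 8 genes of lymphocytes and neutrophils and 12, 10 and 22 of 31 cell death genes. Epas1, a hypoxia-inducible factor, was at -0.97 ± 0.060, and the junction gene Jam2 at -0.68 ± 0.066. In metabolism the counts (higher, lower, over the list alone) were 6, 5 and 11 of 23 glycolysis genes, 2, 9 and 8 of 40 nuclear oxidative phosphorylation genes, 11, 1 and 12 of 24 cholesterol synthesis genes and 7, 4 and 11 of 15 heat shock genes. Hspa1b was at -3.90 ± 0.19. Lists of tissues around the retina had (higher, lower, over the list alone) 1, 1 and 1 of 21 lens genes, 3, 1 and 3 of 19 genes of iris, ciliary body and cornea, 2, 0 and 2 of 12 skeletal muscle genes and 5, 0 and 5 of 8 erythrocyte genes. The 7 named genes had adjusted p from 2.8e-13 to 3.8e-08. Scaled to the bipolar list, the medians of 11 of these 23 lists turned negative (-0.40 to -0.07), and higher and lower genes numbered 0 and 37 for oxidative phosphorylation, 3 and 7 for angiogenic factors, 3 and 4 for matrix, 4 and 13 for cell death, 0 and 12 for cholesterol synthesis, 1 and 15 for circadian clock, 2 and 7 for cones, 2 and 3 for cytokines, 1 and 16 for glycolysis, 2 and 7 for heat shock, 0 and 5 for horizontal cells, 4 and 12 for immediate early genes, 1 and 9 for lens, 10 and 10 for synapses and 2 and 12 for junctions.

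The split between higher and lower genes depended on the scaling. Scaled so that the bipolar cell list stayed level, 9895 genes differed in all light, of which 16.2% were higher, against 50.2% under TMM. With limma-trend on FPKM, scaled by summed counts and written on FPKM below, 70.4% of 9961 were higher. The median of all genes shifted by -0.43 (log2) from TMM to bipolar scaling. Lists of rods, ganglion cells, amacrine cells, microglia, complement, gliosis, pigment epithelium and endothelium kept the sign of their median under both of these in all light. Fewer genes were called higher when scaled to the bipolar list, 10 of 19 amacrine, 7 of 20 Müller glia (3 lower), 7 of 24 endothelial (2 lower), 5 of 34 interferon (5 lower), 6 of 19 bipolar (3 lower) and 5 of 31 antioxidant (7 lower) genes, and 31 unfolded protein genes were lower.

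Rod genes led the falls in Blue200 against control. Gnat1 (-11.83 ± 1.4) and Pde6b (-10.41 ± 1.1) fell, and so did Nr2e3 (-10.37 ± 1.3), Nrl (-10.07 ± 1.1) and Clul1 (-10.03 ± 0.78), adjusted p from 6.0e-08 to 7.6e-06. Pax7 and Btg4 had 0 counts in all 3 libraries and were at least 79.2-fold and 72.1-fold lower. B4galnt2 and Sult1c3 rose from 0.0236 ± 0.0205 and 0.0246 ± 0.0426 CPM to 2.34 ± 3.79 and 2.14 ± 1.93 CPM (SD, n = 3). Other large rises were Krt5 (6.36 ± 2.1), Cyp3a9 (5.88 ± 1.5) and RT1-CE16 (5.25 ± 1.5), then RT1-Bb (5.23 ± 1.3), Slco1a5 (4.61 ± 0.75) and Upk1b (4.57 ± 1.3), adjusted p from 6.8e-05 to 0.018 over all 8. Krt5, a keratin, came mostly from replicate 1, the library with most lens RNA, at 175 CPM against 3.98 and 1.34 CPM in the others. Calls were lost without Blue200 replicate 1 or without the 3 lens-rich libraries for B4galnt2, Krt5, Cyp3a9 and Upk1b (adjusted p from 0.1 to 0.60). With limma-trend on FPKM they were lost for B4galnt2, Krt5 and Cyp3a9 (adjusted p from 0.062 to 0.087). With voom quality weights they were lost for Krt5, Cyp3a9, RT1-CE16, RT1-Bb and Upk1b (adjusted p from 0.066 to 0.34). Krt5 also lost its call without control replicate 1 or 2 or with only the compared groups fitted (adjusted p from 0.061 to 0.11). Rod genes were lower for 34 of 34, 34 over the list alone (camera adjusted p = 3.7e-26; 0.31 with estimated correlation). Ganglion cell genes were higher for 18 of 21 and lower for 1, 21 over the list alone (camera adjusted p = 2.7e-07; 0.31 with estimated correlation). Pigment epithelium genes were higher for 18 of 27 and lower for 1, 20 over the list alone (camera adjusted p = 0.00027; 0.60 with estimated correlation). In Blue200 8559 genes differed, 4428 higher and 4131 lower, 2213 by over 2-fold. In Blue200 under the bipolar scaling 8798 differed, 13.2% higher against 51.7% and 71.2% on FPKM (median shift -0.49).

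In Blue1000 against control rod genes fell as well. They included Gnat1 (-10.72 ± 1.3), Pde6b (-9.62 ± 1.1) and Nrl (-9.51 ± 1.1). Clul1 was at -11.25 ± 0.86, and Acbd7 fell from 8.96 ± 3.15 to 0.0102 ± 0.0177 CPM, adjusted p from 4.7e-08 to 1.0e-05 over these 5 genes. Mgat4d and Btg4 had 0 counts in every Blue1000 library and were at least 117-fold and 68.9-fold lower. Rises were led by Thbs1 (5.47 ± 0.75), RT1-CE16 (5.37 ± 1.5), Sbspon (5.23 ± 0.56) and Kcnj15 (4.85 ± 0.50). RT1-Bb (4.83 ± 1.3), Cpxm2 (4.59 ± 0.65) and Slco1a5 (4.59 ± 0.75) and Asb15 rose too, adjusted p from 1.8e-07 to 0.0071 over all 8. Asb15 stood at 25, 0.15 and 11.6 CPM in the 3 libraries and at 0.0236 ± 0.0205 CPM in control. Asb15, RT1-CE16 and RT1-Bb lost their calls with voom quality weights (adjusted p from 0.19 to 0.50). Genes of the rod list were lower for 34 of 34, 34 over the list alone (camera adjusted p = 1.0e-25; 0.33 with estimated correlation). Ganglion cell genes were higher for 20 of 21 and lower for 1, 21 over the list alone (camera adjusted p = 9.4e-08; 0.33 with estimated correlation). Pigment epithelium genes were higher for 22 of 27 and lower for 1, 23 over the list alone (camera adjusted p = 4.7e-05; 0.58 with estimated correlation). Skeletal muscle genes were higher for 8 of 12, 8 over the list alone (camera adjusted p = 0.031; 0.58 with estimated correlation). Under the bipolar scaling 5 of 12 were higher. In Blue1000 8686 genes differed, 4387 higher and 4299 lower, 2389 by over 2-fold. In Blue1000 under the bipolar scaling 9346 differed, 17.2% higher against 50.5% and 69.5% on FPKM (median shift -0.46).

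In Hal1000 against control Clul1 (-9.88 ± 0.78) and Cnpy1 (-9.69 ± 0.92) fell, as did Mgat4d (from 10.7 ± 0.72 to 0.00974 ± 0.0169 CPM) and Anxa9 (from 24.1 ± 7.49 to 0.0293 ± 0.000908 CPM), adjusted p from 5.1e-08 to 1.0e-04. Pax7, Btg4, Cfap52 and Glp1r had 0 counts in every Hal1000 library and were at least 78.6-fold, 71.5-fold, 53.9-fold and 26.5-fold lower. Rises were led by Hnf4a (5.63 ± 0.78), RT1-Bb (5.36 ± 1.3), Thbs1 (4.97 ± 0.74) and Slco1a5 (4.96 ± 0.76). Cpxm2 (4.63 ± 0.65), Il20ra (4.55 ± 0.58), Myoc (4.48 ± 0.93) and RT1-Ba (4.46 ± 1.0) rose too, adjusted p from 2.0e-06 to 0.0025 over all 8. RT1-Bb and RT1-Ba lost their calls with voom quality weights (adjusted p from 0.12 to 0.18). Rod list genes were lower for 34 of 34, 34 over the list alone (camera adjusted p = 1.5e-24; 0.28 with estimated correlation). Amacrine genes were higher for 16 of 19, 16 over the list alone (camera adjusted p = 3.1e-07; 0.023 with estimated correlation). Microglia genes were higher for 21 of 26, 21 over the list alone (camera adjusted p = 7.7e-06; 0.60 with estimated correlation). Complement genes were higher for 16 of 19, 17 over the list alone (camera adjusted p = 0.00016; 0.60 with estimated correlation). In Hal1000 8650 genes differed, 4366 higher and 4284 lower, 2399 by over 2-fold. In Hal1000 under the bipolar scaling 9413 differed, 14% higher against 50.5% and 69% on FPKM (median shift -0.52).

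In LED200 against control Gnat1 (-7.64 ± 1.2), Cnpy1 (-7.08 ± 0.75), B4galnt3 (-6.93 ± 1.2), Lamb3 (-6.77 ± 0.81) and Btg4 (from 6.29 ± 2.33 to 0.0201 ± 0.0348 CPM) fell, adjusted p from 1.0e-06 to 0.00011. Mgat4d and RT1-M5 had 0 counts in every LED200 library and were at least 119-fold and 27.9-fold lower. Rises were led by Hnf4a (5.54 ± 0.78), RT1-Bb (5.33 ± 1.3), RT1-CE16 (5.18 ± 1.5) and Slco1a5 (4.79 ± 0.76). Lrat (4.62 ± 0.81), RT1-Ba (4.53 ± 1.0), Thbs1 (4.46 ± 0.72) and Cpxm2 (4.41 ± 0.65) rose too, adjusted p from 7.8e-06 to 0.0089 over all 8. B4galnt3, RT1-Bb, RT1-CE16, Slco1a5 and RT1-Ba lost their calls with voom quality weights (adjusted p from 0.054 to 0.39). Rod genes were lower for 34 of 34, 34 over the list alone (camera adjusted p = 2.5e-23; 0.35 with estimated correlation). Ganglion cell genes were higher for 20 of 21 and lower for 1, 21 over the list alone (camera adjusted p = 1.5e-07; 0.35 with estimated correlation). Synapse genes were higher for 17 of 29 and lower for 6, 25 over the list alone (camera adjusted p = 0.034; 0.88 with estimated correlation). Under the bipolar scaling 5 of 21 ganglion cell genes (1 lower) and 1 of 29 synapse genes (10 lower) were higher. In LED200 8354 genes differed, 4239 higher and 4115 lower, 2080 by over 2-fold. In LED200 under the bipolar scaling 9395 differed, 6.64% higher against 50.7% and 69.8% on FPKM (median shift -0.62).

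In LED1000 against control Nr2e3 (-13.88 ± 1.6), Gnat1 (-11.80 ± 1.4), Nrl (-11.51 ± 1.3) and Cnga1 (-11.26 ± 1.0) fell, as did Clul1 (from 207 ± 37.5 to 0.00982 ± 0.017 CPM), adjusted p from 3.4e-08 to 5.8e-06. Mgat4d and Muc3 had 0 counts in every LED1000 library and were at least 122-fold and 92.6-fold lower. Rises were led by RT1-CE16 (6.46 ± 1.5), RT1-Bb (5.35 ± 1.3), Slco1a5 (4.48 ± 0.75) and Thbs1 (4.22 ± 0.72). Sbspon (4.21 ± 0.55), Lrat (4.15 ± 0.80), Neurog2 (4.12 ± 0.54) and Ttr (4.10 ± 0.80) rose too, adjusted p from 3.4e-06 to 0.0026 over all 8. RT1-CE16 and RT1-Bb lost their calls with voom quality weights (adjusted p from 0.17 to 0.29). Genes of rods were lower for 34 of 34, 34 over the list alone (camera adjusted p = 8.3e-26; 0.32 with estimated correlation). Interferon genes were higher for 24 of 34 and lower for 3, 27 over the list alone (camera adjusted p = 0.0014; 0.82 with estimated correlation). Endothelial genes were higher for 21 of 24, 21 over the list alone (camera adjusted p = 1.6e-05; 0.65 with estimated correlation). Pigment epithelium genes were higher for 18 of 27 and lower for 1, 19 over the list alone (camera adjusted p = 0.00016; 0.65 with estimated correlation). In LED1000 8725 genes differed, 4433 higher and 4292 lower, 2420 by over 2-fold. In LED1000 under the bipolar scaling 8176 differed, 24.1% higher against 50.8% and 72.1% on FPKM (median shift -0.31).

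In the 5 light groups other than Hal200 the pigment epithelium gene Rpe65 stood between 43.7 and 67 CPM, against 5.07 ± 3.13 CPM in control and 4.0 ± 2.39 CPM in Hal200. Tested between levels 1000 and 200, skeletal muscle genes in blue light had a median of 2.53 (camera adjusted p = 1.8e-09; 0.13 with estimated correlation). This lay in Blue1000 replicate 2 and the in-between replicate 3: list medians over the Blue200 mean were 0.14, 3.31 and 2.20 in replicates 1, 2 and 3, and Myh4 stood at 0.061, 8.2 and 3.04 CPM. In LED light interferon genes had a median of 0.52 (camera adjusted p = 6.4e-05; 0.85 with estimated correlation) and synapse genes -0.17 (camera adjusted p = 3.0e-05; 0.79 with estimated correlation).

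**Figure D2:**
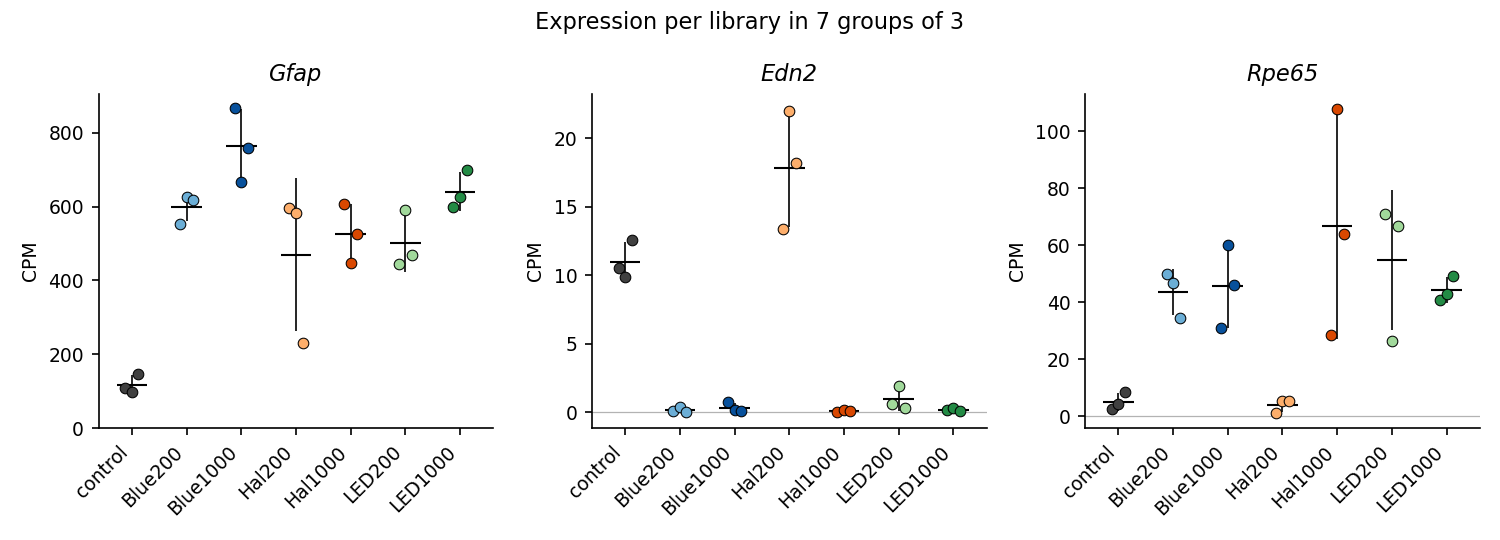
CPM of Gfap, Edn2 and Rpe65 in each of the 21 libraries by group, with points for libraries, horizontal lines for group means and vertical bars for the SD (n = 3). Gfap lies at 117 ± 25.9 CPM in control and 765 ± 100 CPM in Blue1000; the directions of these 3 genes against control do not change under the bipolar scaling in groups where they were called.

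In Hal200 against control glial, immune and class II histocompatibility genes rose while 4 rod genes fell. Rod genes were lower for 4 of 34, 4 over the list alone (camera adjusted p = 1.6e-06; 0.63 with estimated correlation). Among them were Gnb1 (-0.64 ± 0.13) and Rom1 (-0.67 ± 0.14), adjusted p from 0.0043 to 0.0063. The largest rises were RT1-Ba (4.54 ± 1.0), Ca3 (4.11 ± 0.43), Gal (3.97 ± 0.53) and Gli1 (3.79 ± 0.76). RT1-Db1 (3.17 ± 0.72), RT1-Da (3.14 ± 0.81) and Cd74 (3.01 ± 0.67) and Asb15 rose too, adjusted p from 0.00011 to 0.021 over all 8. Asb15 stood at 0.0932, 17.3 and 41.1 CPM in the 3 libraries. Large falls were those of Glp1r (-4.17 ± 1.1), Ccdc125 (-2.10 ± 0.33), Mgat4d (-2.02 ± 0.54) and Rnf183 (-1.97 ± 0.49). Veph1 (-1.85 ± 0.58), Dcst2 (-1.80 ± 0.40) and Adamts7 (-1.69 ± 0.44) fell too, adjusted p from 0.0013 to 0.044 over these 7 genes. Calls were lost without Hal200 replicate 1 for Rom1, RT1-Ba, RT1-Db1, RT1-Da, Cd74, Glp1r, Mgat4d, Rnf183, Veph1 and Adamts7 (adjusted p from 0.052 to 0.13), with limma-trend on FPKM for Asb15 and Veph1 (adjusted p from 0.070 to 0.39) and with voom quality weights for Asb15, RT1-Ba, RT1-Da and Veph1 (adjusted p from 0.054 to 0.59). They were lost also without the 3 in-between libraries for Asb15, RT1-Da, Glp1r, Mgat4d and Veph1 (adjusted p from 0.052 to 0.093), without the 3 lens-rich libraries for Asb15, RT1-Da and Veph1 (adjusted p from 0.054 to 0.29) and without control replicate 1 for Asb15, RT1-Ba, RT1-Da, Cd74, Glp1r, Mgat4d, Rnf183 and Adamts7 (adjusted p from 0.051 to 0.15). Calls were also lost without control replicate 2 for Asb15, Cd74, Glp1r, Mgat4d and Adamts7 (adjusted p from 0.055 to 0.090), without control replicate 3 for RT1-Da and Veph1 (adjusted p from 0.052 to 0.40) and without Hal200 replicate 2 for RT1-Da, Glp1r, Mgat4d, Rnf183, Veph1 and Adamts7 (adjusted p from 0.053 to 0.12). Calls were lost too with DESeq2 for Glp1r (adjusted p = 0.52) and without Hal200 replicate 3 for Veph1 (adjusted p = 0.097). With edgeR fitted to the 6 compared libraries alone none of the genes named here was called.

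Several lists also differed between Hal200 and control. Ganglion cell genes were higher for 15 of 21, 20 over the list alone (camera adjusted p = 3.3e-13; 0.099 with estimated correlation). Microglia genes were higher for 16 of 26, 21 over the list alone (camera adjusted p = 2.1e-10; 0.48 with estimated correlation). Gliosis genes were higher for 15 of 33, 18 over the list alone (camera adjusted p = 2.1e-10; 0.33 with estimated correlation). Complement genes were higher for 11 of 19, 11 over the list alone (camera adjusted p = 1.0e-07; 0.48 with estimated correlation). Antigen presentation genes were higher for 8 of 20, 9 over the list alone (camera adjusted p = 0.00062; 0.63 with estimated correlation). With the bipolar list held level 9 of 21 ganglion cell genes were higher. Their members included A2m at 1.65 ± 0.13, the oncostatin receptor Osmr at 1.83 ± 0.24, Ptprc at 1.93 ± 0.31 and C4b at 2.11 ± 0.29, adjusted p from 2.7e-06 to 0.0013. These genes lost their calls with only the compared groups fitted (adjusted p from 0.053 to 0.079). Of 27 pigment epithelium genes 1 was higher and 1 lower, 2 adjusted over the list alone. In total 1897 genes differed, 1160 higher and 737 lower, 269 by over 2-fold. With the bipolar list held level 1869 differed, 19.4% higher against 61.1% and 77.3% on FPKM, with a median shift of -0.15. The count fell to 0 with edgeR fitted to the 6 compared libraries alone, against 4452 at an unadjusted p under 0.05 with all 21. It was 2499 with DESeq2, 2195 with limma-trend on FPKM and 4750 with voom quality weights. Without Hal200 replicates 1, 2 and 3 in turn it was 402, 757 and 3184, and without control replicates 1 and 2 it was 735 and 747. Without the 3 in-between libraries it was 993, and without the 3 lens-rich ones 3028.

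Genes tied to the barrier and to retinal stress, fixed in advance, were read in every light group. Gfap, a filament of reactive glia, rose in all 6 groups, from 2.01 ± 0.27 in Hal200 to 2.71 ± 0.28 in Blue1000, adjusted p from 5.1e-07 to 0.00099. Edn2 (endothelin 2) and Fgf2 are both induced by photoreceptor damage. In the 5 groups other than Hal200 they were lower, between -7.25 and -3.57 for Edn2 and between -1.94 and -1.18 for Fgf2, adjusted p from 9.3e-06 to 0.00066 and from 3.7e-06 to 0.00056. Rod list medians there were at most 5% of control, so the falls do not show less damage. In Hal200 Edn2 was at 0.70 ± 0.65, adjusted p = 0.52, and Fgf2 at 0.57 ± 0.25, adjusted p = 0.13. The pigment epithelium isomerase gene Rpe65 rose in the same 5 groups, between 3.10 and 3.71, adjusted p from 0.00012 to 0.00053, and was at -0.35 ± 0.61, adjusted p = 0.76 in Hal200. Tested directly, Hal1000 against Hal200 differed in Edn2 (-7.95 ± 1.0, adjusted p = 1.0e-05), Fgf2 (-1.83 ± 0.25, adjusted p = 1.5e-05) and Rpe65 (4.07 ± 0.63, adjusted p = 0.00014). Gfap was at 0.17 ± 0.26, adjusted p = 0.67 in that comparison. The microglial marker Aif1 was higher in Blue200, Blue1000, Hal1000 and LED200, between 0.96 and 1.13, adjusted p from 0.013 to 0.034. It was at 0.84 ± 0.36, adjusted p = 0.057 in LED1000 and at 1.01 ± 0.36, adjusted p = 0.076 in Hal200, and between levels it had adjusted p from 0.83 to 0.98. Gfap lost its call in Hal200 with only the compared groups fitted (adjusted p = 0.089). Edn2 and Fgf2 were called in Hal200 with voom quality weights (adjusted p from 0.0026 to 0.0065). Aif1 lost its call in Blue200 and LED200 with only the compared groups fitted, in Blue200, Blue1000 and LED200 without the 3 lens-rich libraries, in Blue200, Blue1000, Hal1000 and LED200 without control replicate 3 or scaled to the bipolar list, in Blue200 without Blue200 replicate 1 or 2, in Blue1000 and LED200 without the 3 in-between libraries, in Blue1000 without Blue1000 replicate 1, and in LED200 without control replicate 2, without LED200 replicate 2 or with voom quality weights (adjusted p from 0.054 to 0.44). Aif1 was called in Hal200 without Hal200 replicate 3, with DESeq2 or with voom quality weights, and in LED1000 without LED1000 replicate 1 or with limma-trend on FPKM (adjusted p from 0.018 to 0.047).

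Among tight junction genes, Tjp1, which encodes the scaffold ZO-1, was at -0.32 ± 0.098 (adjusted p = 0.011) in Blue200 and -0.24 ± 0.098 (adjusted p = 0.046) in Blue1000. It was at -0.36 ± 0.098 (adjusted p = 0.0048) in Hal1000 and -0.37 ± 0.098 (adjusted p = 0.0033) in LED1000. In LED200 it was at -0.22 ± 0.098, adjusted p = 0.070 and in Hal200 at -0.11 ± 0.098, adjusted p = 0.49, neither called, and on average over the 6 groups it was at -0.27 ± 0.073, adjusted p = 0.0038. Between levels it was not called, adjusted p from 0.063 to 0.90. Tjp1 lost its call in Blue200, Blue1000, Hal1000 and LED1000 and on average with limma-trend on FPKM, in Blue200 without Blue200 replicate 1 or without the 3 lens-rich libraries, in Blue200 and Blue1000 without control replicate 2, and in Blue1000 without Blue1000 replicate 1, 2 or 3, without control replicate 1, without the filter on low counts or without the 3 in-between libraries (adjusted p from 0.052 to 0.94). Tjp1 was called in LED200 without control replicate 3 or with DESeq2 size factors, and in LED200 and between halogen levels with DESeq2, with only the compared groups fitted, with voom quality weights, without the 3 lens-rich libraries or scaled to the bipolar list (adjusted p from 5.0e-08 to 0.049). Cldn5, the claudin of endothelial tight junctions, was at 0.64 ± 0.19 (adjusted p = 0.0092) in Blue200, 0.76 ± 0.19 (adjusted p = 0.017) in Hal200 and 0.48 ± 0.19 (adjusted p = 0.042) in Hal1000. It was at 0.68 ± 0.19 (adjusted p = 0.0061) in LED200 and 1.0 ± 0.19 (adjusted p = 0.00025) in LED1000. In Blue1000 it was at 0.44 ± 0.19, adjusted p = 0.065, on average over the 6 groups at 0.67 ± 0.16, adjusted p = 0.0011, and between levels it had adjusted p from 0.29 to 0.86. Under the bipolar scaling Cldn5 in Hal1000 turned to -0.05. Cldn5 lost its call in Blue200, Hal200, Hal1000 and LED200 and on average scaled to the bipolar list, in Hal200 and Hal1000 without control replicate 1 or 2 or with only the compared groups fitted, in Hal200 without Hal200 replicate 1 or 2, and in Hal1000 without Hal1000 replicate 1 or 3 or without the 3 in-between libraries (adjusted p from 0.051 to 0.87). Cldn5 was called in Blue1000 without Blue1000 replicate 1, without control replicate 3, with limma-trend on FPKM, with voom quality weights or without the 3 lens-rich libraries, and between halogen levels and between LED levels scaled to the bipolar list (adjusted p from 0.0067 to 0.041). Ocln (occludin) was called in none of the 6 groups in the fit to all libraries, adjusted p from 0.17 to 0.99. Ocln was called in Blue200, LED200 and LED1000 without control replicate 3, in Blue1000, Hal1000 and LED1000 without the 3 lens-rich libraries, in LED200 and LED1000 with voom quality weights, and in LED1000 with limma-trend on FPKM (adjusted p from 0.0012 to 0.044).

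Plvap, an endothelial gene, was at 0.79 ± 0.19 (adjusted p = 0.0014) in Blue1000, 0.87 ± 0.19 (adjusted p = 0.00061) in Hal1000 and 0.46 ± 0.19 (adjusted p = 0.042) in LED1000. Neither leakage nor tissue carried along at dissection was tested for this gene. In the groups at 200 it was not called, adjusted p from 0.058 to 0.31, and on average over the 6 groups it was at 0.54 ± 0.15, adjusted p = 0.0043. Level 1000 against 200 was called for halogen (0.57 ± 0.18, adjusted p = 0.022), with 0.43 ± 0.18, adjusted p = 0.85 in blue and 0.03 ± 0.18, adjusted p = 0.95 in LED light. Plvap lost its call in Blue1000, Hal1000 and LED1000 and on average and between halogen levels scaled to the bipolar list, in LED1000 without control replicate 3, without LED1000 replicate 2 or 3, with DESeq2 size factors, with DESeq2, with only the compared groups fitted, without the 3 in-between libraries or without the 3 lens-rich libraries, in LED1000 and on average without control replicate 1, and between halogen levels without Hal200 replicate 1 or 2 or without Hal1000 replicate 1 (adjusted p from 0.054 to 0.57). Plvap was called in Blue200 and LED200 with limma-trend on FPKM or with voom quality weights, and in LED200 without control replicate 2 or without LED200 replicate 1 or 2 (adjusted p from 0.0061 to 0.048). Vegfa, the vascular growth factor, was called in LED1000 (0.26 ± 0.090, adjusted p = 0.019), and level 1000 against 200 was at 0.37 ± 0.090, adjusted p = 0.0032 in halogen, 0.06 ± 0.090, adjusted p = 0.92 in blue and 0.26 ± 0.090, adjusted p = 0.26 in LED light. Under the bipolar scaling Vegfa turned to -0.04 in LED1000 and to -0.0036 in the halogen level comparison. Vegfa lost its call in LED1000 without control replicate 3, with only the compared groups fitted, without the 3 in-between libraries or without the 3 lens-rich libraries, and in LED1000 and between halogen levels scaled to the bipolar list (adjusted p from 0.063 to 0.99). Vegfa was called between LED levels with voom quality weights or scaled to the bipolar list (adjusted p from 0.011 to 0.023). The cone opsin gene Opn1sw was called in none of the 6 groups in the fit to all libraries, adjusted p from 0.061 to 0.59. Opn1sw was called in LED200 and LED1000 without control replicate 1, with only the compared groups fitted or with limma-trend on FPKM (adjusted p from 0.012 to 0.036).

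The tight and adherens junction list held 28 tested genes. Counted as higher, as lower and as called adjusted over the list alone, there were 10, 5 and 15 in Blue200, 8, 5 and 11 in Blue1000 and 2, 1 and 3 in Hal200. In the other groups these 3 counts were 7, 5 and 11 in Hal1000, 7, 4 and 11 in LED200 and 8, 5 and 13 in LED1000. The balance turned when scaled to the bipolar list. Higher and lower genes then numbered 3 and 10 in Blue200, 3 and 9 in Blue1000 and 0 and 1 in Hal200. They numbered 1 and 11 in Hal1000, 1 and 13 in LED200 and 4 and 9 in LED1000. Camera called the list in none of the 6 groups, adjusted p from 0.45 to 0.97.

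**Figure D3:**
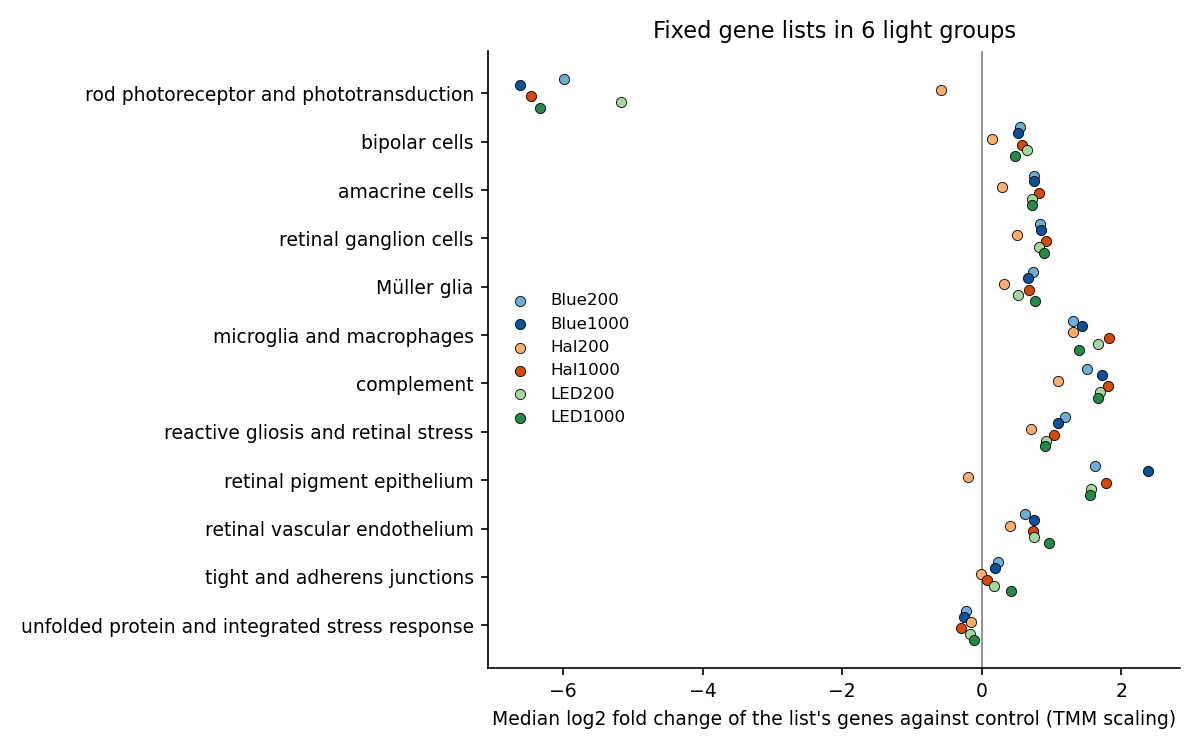
Median log2 fold change against control of 12 gene lists in each of the 6 light groups under TMM scaling. The rod list lies between -6.62 and -5.17 in 5 groups and at -0.59 in Hal200. Under the bipolar scaling the median of the tight junction list changes sign in most groups and that of Müller glia in LED200.

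The light groups were compared with each other through their changes against control. 3081 genes were higher and 3288 lower in each of the 5 groups other than Hal200. Of the genes called in Hal200, 1042 of 1160 higher and 687 of 737 lower ones were called the same way in all 5. Kremen1, Cd1d1, Sec16b and Eml2, chosen after their values were seen, were higher in Hal200 and lower in each of the 5. In Hal200 they were at 0.73 ± 0.12, 1.59 ± 0.43, 0.89 ± 0.28 and 0.23 ± 0.069, adjusted p from 0.0014 to 0.043, and Kremen1 lay between -0.87 and -0.73 in the 5. Kremen1 lost its call with only the compared groups fitted (adjusted p = 0.077). Cd1d1 lost its call without control replicate 1 or 2, without Hal200 replicate 2 or with only the compared groups fitted (adjusted p from 0.077 to 0.095). Sec16b lost its call without control replicate 2 or 3, without Hal200 replicate 1 or 2, with only the compared groups fitted, without the 3 in-between libraries, without the 3 lens-rich libraries or scaled to the bipolar list (adjusted p from 0.062 to 0.18). Eml2 lost its call without control replicate 1, 2 or 3, without Hal200 replicate 2 or 3, with DESeq2 size factors, with only the compared groups fitted, without the 3 in-between libraries, without the 3 lens-rich libraries or scaled to the bipolar list (adjusted p from 0.060 to 0.58). Across genes, log2 fold changes of the 5 groups correlated with r = 0.817 to 0.906 between pairs, where simulated unchanged groups with the same controls gave 0.502 to 0.523. Pairs with Hal200 gave r = 0.469 to 0.582 against 0.508 to 0.517. The covariance exceeded the simulated one by 0.876 to 1.11 in the first pairs and by 0.261 to 0.367 in those with Hal200. Genes are not independent replicates, and since 3 controls cannot be split into 2 sets of 2, part of the overlap may come from the shared controls. Independent lists of the same sizes would share 1156 to 1226 higher genes between pairs of the 5, where 3489 to 3869 were shared.

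Level 1000 against 200 differed mainly for halogen light. Rod genes were lower for 34 of 34, 34 over the list alone (camera adjusted p = 8.4e-36; 0.13 with estimated correlation). Pax7, Cfap52, Btg4 and Mgat4e had 0 counts in every Hal1000 library and were at least 101-fold, 64.4-fold, 27.4-fold and 26.8-fold lower than in Hal200. Clul1 (-9.31 ± 0.77) and Nr2e3 (-8.76 ± 1.2) fell, as did Anxa9 (from 17.1 ± 5.15 to 0.0293 ± 0.000908 CPM) and Asb15 (from 19.5 ± 20.6 to 0.0196 ± 0.017 CPM), adjusted p from 2.5e-07 to 0.0045. Rises were led by Hnf4a (from 0.0307 ± 0.0311 to 2.55 ± 1.44 CPM), Il20ra (5.29 ± 0.61), Thbs1 (4.97 ± 0.73) and Tspan10 (4.95 ± 0.83). Slco1a5 (4.71 ± 0.73), Cr2 (4.62 ± 0.90), Mlana (4.51 ± 1.1) and Rdh5 (4.46 ± 0.77) rose too, adjusted p from 1.8e-06 to 0.0035 over all 8. Asb15 and Mlana lost their calls with voom quality weights (adjusted p from 0.055 to 0.41). Pigment epithelium genes were higher for 19 of 27 and lower for 1, 21 over the list alone (camera adjusted p = 6.0e-07; 0.50 with estimated correlation). Amacrine genes were higher for 15 of 19, 16 over the list alone (camera adjusted p = 3.6e-07; 0.022 with estimated correlation). In halogen light 5589 genes differed between levels, 2641 higher and 2948 lower. With the bipolar list held level 7091 differed, 4.7% higher against 47.3% and 66.4% on FPKM, with a median shift of -0.37.

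In blue light 2 genes differed between levels, both lower at 1000. They were Dio2, the deiodinase that activates thyroid hormone (-1.23 ± 0.18, adjusted p = 0.015), and Vgf, a secreted neuropeptide precursor (-0.57 ± 0.084, adjusted p = 0.015). Dio2 lost its call without Blue200 replicate 3, without Blue1000 replicate 2 or 3, with only the compared groups fitted or without the 3 in-between libraries (adjusted p from 0.060 to 0.88). Vgf lost its call without Blue200 replicate 1 or 3, without Blue1000 replicate 2 or 3, with only the compared groups fitted, with limma-trend on FPKM, without the 3 in-between libraries, without the 3 lens-rich libraries or scaled to the bipolar list (adjusted p from 0.053 to 0.79). The count was 0 without Blue1000 replicate 2, Blue1000 replicate 3 or Blue200 replicate 3 and 9 without Blue1000 replicate 1. It was 17 with DESeq2, 64 with voom quality weights, 1 with limma-trend on FPKM and 861 at an unadjusted p under 0.05 in edgeR. With only the compared groups fitted, or without the 3 in-between libraries, it was 0, and scaled to the bipolar list 1.

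In LED light 11 genes differed between levels. Dio2 and Vgf rose here, at 0.99 ± 0.17 and 0.63 ± 0.084. Other rises were those of Sat1, which acetylates polyamines (0.77 ± 0.13), the neuropeptide gene Cartpt (0.69 ± 0.13), Espn (0.61 ± 0.099) and Lgi4 (0.56 ± 0.076). Pgm2l1 (-0.62 ± 0.099) and Prima1 (-0.56 ± 0.10) fell, adjusted p from 0.0026 to 0.047 over all 8. Calls were lost with only the compared groups fitted for Dio2, Sat1, Cartpt, Espn, Lgi4, Pgm2l1 and Prima1 (adjusted p from 0.098 to 0.18). Without the 3 in-between libraries they were lost for Dio2, Sat1, Cartpt, Vgf, Espn, Lgi4, Pgm2l1 and Prima1 (adjusted p from 0.099 to 0.50). They were lost also without LED200 replicate 2 for Dio2, Sat1 and Cartpt (adjusted p from 0.051 to 0.092), without LED200 replicate 3 for Dio2, Cartpt, Espn, Pgm2l1 and Prima1 (adjusted p from 0.059 to 0.15) and without LED1000 replicate 1 for Dio2 and Prima1 (adjusted p from 0.062 to 0.068). Calls were also lost without LED1000 replicate 2 for Dio2, Sat1, Cartpt, Espn, Pgm2l1 and Prima1 (adjusted p from 0.094 to 0.20), without LED1000 replicate 3 for Dio2, Sat1, Cartpt, Espn, Pgm2l1 and Prima1 (adjusted p from 0.14 to 0.26) and with limma-trend on FPKM for Cartpt and Prima1 (adjusted p from 0.055 to 0.082). Prima1 also lost its call scaled to the bipolar list (adjusted p = 0.11). The count was 3 without LED1000 replicate 2, 3 without LED1000 replicate 3 and 4 without LED200 replicate 1. It was 0 without the 3 in-between libraries, 66 without the lens-rich ones, 168 with DESeq2 and 1158 with voom quality weights, against 2332 at an unadjusted p under 0.05 in edgeR and 12 with limma-trend on FPKM. With the bipolar list held level 4750 genes differed, 99.1% higher against 72.7%, 91.7% on FPKM, 36.9% with DESeq2 and 32.5% with voom quality weights, with a median shift of 0.31.

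Over the 3 sources together, level 1000 against 200 changed 2439 genes, 923 higher and 1516 lower. The 5 genes with the smallest adjusted p were Rom1 (-1.25 ± 0.082), Elovl4 (-0.87 ± 0.060), Rhpn1 (-1.37 ± 0.094), Gnb1 (-1.04 ± 0.074) and Amotl2 (-0.70 ± 0.052), adjusted p from 6.8e-08 to 9.9e-08. Rom1 and Gnb1 encode outer segment and transducin proteins of rods, and Elovl4 a fatty acid elongase of photoreceptors. All 5 were lower at 1000, and among the groups at 200 the rod share of counts was above 1% in Hal200 alone. Without the 3 in-between libraries 1250 genes differed, and with voom quality weights 4904. Scaled to the bipolar list 26.9% of 1846 were higher, and on FPKM 62.4% of 3022, against 37.8%.

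Averaged over levels, blue and LED light each differed from halogen light in rod genes. This lay in Hal200, where they took 5.93% of counts, against 0.167 to 0.185% in the groups at 1000. Of rod genes 34 of 34 were lower in blue against halogen light and higher in halogen against LED light, 34 over the list alone. Camera adjusted p was 4.8e-45 and 4.7e-39 (0.074 and 0.13 with estimated correlation). Between blue and halogen light the smallest adjusted p belonged to Elovl4 (-1.25 ± 0.073), Gnb1 (-1.52 ± 0.092), Rom1 (-1.71 ± 0.10), Bbs9 (-1.41 ± 0.089) and Osbp2 (-1.14 ± 0.075), adjusted p from 5.6e-09 to 1.3e-08. Between halogen and LED light they were those of Elovl4 (1.20 ± 0.073), Gnb1 (1.48 ± 0.092), Rom1 (1.54 ± 0.10), Osbp2 (1.07 ± 0.075) and Tob2 (1.14 ± 0.082), adjusted p from 1.3e-08 to 5.3e-08. 2778 genes differed in the first comparison, 1029 higher and 1749 lower, and 2803 in the second, 1717 higher and 1086 lower. Scaled to the bipolar list 5.77% and 95.8% of calls were higher, and on FPKM 62% and 33.5%, against 37% and 61.3%, with median shifts of -0.14 and 0.13. Leaving out the 3 in-between libraries, the counts were 1333 and 1463, and with voom quality weights 5592 and 4806.

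Blue against LED light gave 0 genes with edgeR, 1393 at an unadjusted p under 0.05, 54 with DESeq2, 1190 with voom quality weights and 0 with limma-trend on FPKM. The smallest p values, none of them called, belonged to a provisional gene and 4 others. These were Itgb4 (0.80 ± 0.16), Kcnj10 (0.26 ± 0.052), Ngfr (0.45 ± 0.092) and the cone phosphodiesterase gene Pde6h (-0.66 ± 0.14), each with adjusted p = 0.23. Itgb4 and Pde6h were called without Blue1000 replicate 1, with DESeq2 or with voom quality weights (adjusted p from 0.0039 to 0.036). Kcnj10 and Ngfr were called with DESeq2 or with voom quality weights (adjusted p from 0.0022 to 0.0063). The count was 1 without LED200 replicate 2, 2 without Blue1000 replicate 1 and 10 without Blue200 replicate 1, and 4 without the lens-rich libraries. Cone genes had a median of -0.40 with 0 of 16 called, 6 adjusted over the list alone (camera adjusted p = 6.4e-08; 0.54 with estimated correlation).

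The level effect was tested for a difference between sources. Against halogen light it differed in 3310 genes for blue light and in 3427 for LED light, led by photoreceptor genes. For blue minus halogen these were Elovl4 (2.51 ± 0.15), Rom1 (3.47 ± 0.20), Gnb1 (2.91 ± 0.18), Osbp2 (2.27 ± 0.15) and Bicdl1 (2.37 ± 0.17), adjusted p from 6.8e-09 to 3.2e-08. For halogen minus LED they were Rom1 (-3.25 ± 0.20), Gnb1 (-2.69 ± 0.18), Elovl4 (-2.14 ± 0.15), Bicdl1 (-2.38 ± 0.17) and Lpcat1 (-1.98 ± 0.15), adjusted p from 4.0e-08 to 1.3e-07. Of these differences 57.7% and 48.7% were positive, against 97.5% of 5196 and 1.2% of 8745 scaled to the bipolar list and 36.5% and 60.4% on FPKM, with median shifts of 0.40 and -0.69. Without the 3 in-between libraries the counts were 1867 and 1924, and with voom quality weights 5394 and 5470.

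Between blue and LED light the level effect differed in 10 genes, 3 of them positive. Those with the smallest adjusted p included Vgf (-1.20 ± 0.12, adjusted p = 6.9e-05), Dio2 (-2.22 ± 0.25, adjusted p = 0.00024), the chemokine Cxcl14 (-0.73 ± 0.10, adjusted p = 0.0034) and the vesicular monoamine transporter Slc18a2 (-2.22 ± 0.35, adjusted p = 0.016). Cxcl14 lost its call without the 3 in-between libraries (adjusted p = 0.090). Slc18a2 lost its call without Blue1000 replicate 2 or 3, without LED1000 replicate 3, with only the compared groups fitted or without the 3 in-between libraries (adjusted p from 0.051 to 0.31). Without 1 library the count ranged from 4 to 25. It was 105 with DESeq2, 755 with voom quality weights, 3 with only the compared groups and 2 without the 3 in-between libraries. Under the bipolar scaling it was 34, 5.88% of them positive, with a median shift of -0.28. Any difference between the 7 groups was found for 8728 genes.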

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

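Of the tests in this part, those on the 3 libraries between their group mates, on the lower rod share and the amount of pigment epithelium RNA, and on Hal200 were chosen only after the result was seen, as were the regroupings of the libraries for the comparisons with control, for level within a source and for any difference, and the look at the Hal200 libraries in them.

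The level effect differed between light sources by a test of the difference itself. Between blue and halogen light it differed in 3310 genes, led by Elovl4, Rom1, Gnb1, Osbp2 and Bicdl1 with log2 differences of 2.51, 3.47, 2.91, 2.27 and 2.37. Between halogen and LED light it differed in 3427 genes, led by Rom1 (-3.25), Gnb1 (-2.69), Elovl4 (-2.14), Bicdl1 (-2.38) and Lpcat1 (-1.98). Between blue and LED light it differed in 10 genes, among them Vgf (-1.20), Dio2 (-2.22), Cxcl14 (-0.73) and Slc18a2 (-2.22).

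Libraries were regrouped to see how many genes other splits call. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split gave the most genes (1 of 10) in each of these 9 comparisons, with real value and highest other of 8559 and 1 for Blue200, 8686 and 0 for Blue1000, 1897 and 1761 for Hal200, 8650 and 0 for Hal1000, 8354 and 58 for LED200, 8725 and 0 for LED1000 against control, 2 and 1 for level in blue light, 5589 and 0 for level in halogen light and 11 and 0 for level in LED light. Chance could be excluded for all light against control (1 of 100 splits, 9378 genes against at most 1585 in another). The same held for any difference (1 of 100, 8728 against at most 3991). For the blue-LED level effect the real split also called the most genes (1 of 25, 10 against at most 1). These splits regrouped the halogen libraries too, and 2 of the 24 others kept Hal200 together. The spread shared by all groups thus changed with them, so they could not decide. Splits could not decide for level over the sources (1 of 25, 2439 against at most 2304). Nor could they for the blue-halogen level effect (1 of 25, 3310 against at most 3153). The splits with 2304 and 3153 genes kept Hal200 together, and those that parted it called at most 1 and 0. For blue against LED light (25 of 25, up to 21 genes) splits say nothing, as any calls at least the real 0. They could not decide for blue against halogen light (3 of 25, 2778 genes against up to 3053), halogen against LED light (2 of 25, 2803 genes against up to 2806) and the level effect between halogen and LED light (2 of 25, 3427 genes against up to 3945), since the other splits as large all kept the Hal200 libraries together, and those that parted them called at most 0, 2 and 1 genes.

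Blue1000 replicate 3, Hal1000 replicate 3 and LED1000 replicate 2 lay between the other 2 libraries of their group for 735 of the 737 genes that differed between those 2 (99.73%). This is in line with a mixture of the RNA or reads of the other 2, since the weights of these genes had an interquartile range of at most 0.16. A chance position of independent samples cannot be told apart from it: the 3 were picked by this share, so that the others (at most 94.08%) had to lie lower, and among 3728 triples across groups it reached 100%. 0 of these triples joined over 99% with a weight from 0.25 to 0.75 and an interquartile range under 0.2, as all 3 did. Outside the mates' span lay 8, 11 and 7 genes (59 to 1662 in the other 18). Neither decides, given how the 3 were picked. For 6 rod genes of Hal1000 replicate 3 a plain mixture was argued against, as they stood at a median of 13.6% of the lower of the other 2; how the libraries were made stays open, and no biological explanation was tested, since the labels name none.

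The pigment epithelium list was higher in the 5 light groups other than Hal200. A lower rod share alone was argued against: it would raise all other cell types alike, yet the list's median log2 ratio exceeded that of the bipolar cell list by 1.30 more in the 15 libraries than in the 3 controls (exact permutation test, two-sided, p = 0.0074, 816 permutations). Pigment epithelium carried along at dissection may contribute, since the 27 genes rose and fell together between libraries of 1 group, with a mean pairwise correlation across libraries of 0.473 against at most 0.111 in 1000 random lists of like expression. More pigment epithelium RNA in the light-exposed tissue itself cannot be told apart from it: 15 of 15 libraries lay above the highest control by the list's share of counts, which rod loss raises too, and 10 by the difference to the bipolar list, which both would give.

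Hal200 stood apart from the other light groups in its rod genes. A plain mixture of control-like and rod-depleted retina was argued against for microglia genes: rod genes gave depleted shares of 49.6, 32.3 and 14.4%, at which the depleted part would need microglia genes at a median of 6.11, 7.44 and 3.42 times control, against 1.85 to 4.42 in the 15 rod-depleted libraries, and 2 of 3 libraries lay above these also at the upper quartile of the share. Gliosis and ganglion cell genes leave it open, with 2 of 6 such values above those of the 15 (1 in each list); pigment epithelium genes would need less than any of the 15 held in all 3, and 1268 of 1326 genes called against both control and Hal1000 lay between them. Labels of 1 or 2 libraries swapped with another light group were argued against, as 0 libraries of the other light groups held rod list genes at a median above 10% of the control mean, against 47.5, 64.7 and 83.7% in the 3 Hal200 libraries; labels of all 3 swapped with another group cannot be told apart from none, since the values would be the same. An effect of the light itself stays open as untested, as does a mixture with a depleted part unlike those 15.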

How the results depend on the processing

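The alternatives without the 3 libraries between their group mates, without the 3 lens-rich ones or scaled to the bipolar cell list were chosen only after the data were seen. Counts of genes for the 5 groups against control other than Hal200, for all light, for level in halogen light and for any difference stayed within 1.5 times the value given above under every alternative that counted them (log2(FPKM + 0.1) was run for named genes alone, the fit of compared groups not for all light or any difference) and without each compared library. Of the named genes and comparisons, 271 of 280 kept direction and side of the threshold with DESeq2, 237 of 280 with voom quality weights, 255 of 280 scaled to the bipolar list, 181 of 231 with only the compared groups fitted and 2431 of 2568 values without 1 library.

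With DESeq2 the counts were 17 for level in blue light, 168 for level in LED light, 54 for blue against LED light and 105 for the level effect between blue and LED light. With only the compared groups in the fit, and so fewer libraries, the counts were 0 for Hal200, 0 for level in blue light and 3 for the level effect between blue and LED light. With limma-trend on log2(FPKM + 1) the counts were 1 for level in blue light. With limma voom and quality weights the counts were 4750 for Hal200, 64 for level in blue light, 1158 for level in LED light, 4904 for level over the sources, 5592 for blue against halogen light, 1190 for blue against LED light, 4806 for halogen against LED light, 5394 for the level effect between blue and halogen light, 755 for the level effect between blue and LED light and 5470 for the level effect between halogen and LED light. Without the 3 libraries between their group mates the counts were 993 for Hal200, 0 for level in blue light, 0 for level in LED light, 1250 for level over the sources, 1333 for blue against halogen light, 1463 for halogen against LED light, 1867 for the level effect between blue and halogen light, 2 for the level effect between blue and LED light and 1924 for the level effect between halogen and LED light. Without the 3 lens-rich libraries the counts were 3028 for Hal200, 66 for level in LED light and 4 for blue against LED light. Scaled to the bipolar cell list the counts were 1 for level in blue light, 4750 for level in LED light, 5196 for the level effect between blue and halogen light, 34 for the level effect between blue and LED light and 8745 for the level effect between halogen and LED light. Without 1 library at a time the counts ranged from 0 to 9 for level in blue light, 0 to 10 for blue against LED light, 4 to 25 for the level effect between blue and LED light, 402 to 3184 for Hal200 and 3 to 16 for level in LED light. Scaled to the bipolar cell list these log2 fold changes took the other sign: -0.0506 for Cldn5 (Hal1000), -0.0414 for Vegfa (LED1000) and -0.0036 for Vegfa (level in halogen light).

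With an estimated correlation camera called 1 list for Blue200, Blue1000, Hal1000, LED200, all light against control, level in halogen light, the level effect between blue and halogen light and the level effect between halogen and LED light and 0 lists in the other 9 comparisons, where the preset correlation called 4 to 15 and fry 0 to 20. On log2(FPKM + 1) the counts of lists were 7 for level in blue light and 8 for halogen against LED light.

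Replicate numbers did not pair the samples: deviations of samples with the same number correlated across genes with r from -0.37 to 0.40 (median 0.0053), and 6 of 21 libraries correlated best with their own number. With the replicate number as a block the counts of genes were 3 for level in LED light and 6 for the level effect between blue and LED light; all other counts stayed within 1.5 times. Named genes called in the main fit and not with the block were Krt5 (Blue200), Tjp1 (Blue1000), Eml2, Glp1r and Veph1 (Hal200), Cldn5 (Hal1000), Plvap (LED1000) and Cartpt, Dio2, Espn, Pgm2l1, Prima1 and Sat1 (level in LED light), adjusted p from 0.051 to 0.10, with Krt5 at 4.34; Aif1 (LED1000) was called with the block and not in the main fit, adjusted p = 0.037.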

Other observations

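The genes in this part were chosen only after their values were seen, and no explanation was tested.

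Dio2, Vgf and Slc18a2 were read in all 7 groups. Dio2 stood at 13 ± 1.99 CPM in control, 32.7 ± 8.99 CPM in Blue200, 14 ± 2.27 CPM in Blue1000, 18.5 ± 1.37 CPM in Hal200, 40.2 ± 1.86 CPM in Hal1000, 15.4 ± 3.32 CPM in LED200 and 30.8 ± 0.349 CPM in LED1000 (SD, n = 3). Vgf stood at 70.6 ± 6.9 CPM in control, 112 ± 11.7 CPM in Blue200, 75.6 ± 1.37 CPM in Blue1000, 77.4 ± 8.11 CPM in Hal200, 126 ± 5.7 CPM in Hal1000, 80.5 ± 1.21 CPM in LED200 and 125 ± 2.45 CPM in LED1000. Slc18a2 stood at 2.39 ± 0.546 CPM in control, 7.18 ± 1.97 CPM in Blue200, 3.78 ± 0.129 CPM in Blue1000, 1.49 ± 0.0979 CPM in Hal200, 10.7 ± 1.72 CPM in Hal1000, 3.25 ± 1.33 CPM in LED200 and 8.03 ± 0.533 CPM in LED1000. The 3 genes thus had their highest means in Blue200, Hal1000 and LED1000, and the level effect on each differed between blue and LED light in edgeR.

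Some genes peaked in Hal200. Gal rose by 3.97 ± 0.53 against control and changed by -4.24 ± 0.54 from Hal200 to Hal1000; the monocarboxylate transporter Slc5a8 by 2.92 ± 0.47 and -3.06 ± 0.47, the interleukin 4 receptor Il4r by 2.84 ± 0.44 and -2.06 ± 0.43, and Bcl3, an NF-kappa-B regulator, by 1.87 ± 0.28 and -1.23 ± 0.27 (log2, ± SE; adjusted p from 0.00057 to 0.0019 and adjusted p from 5.8e-06 to 0.0015 in edgeR). With only the compared groups fitted, calls against control were lost for Gal, Slc5a8, Il4r and Bcl3 (adjusted p from 0.053 to 0.14). The call from Hal200 to Hal1000 was lost there for Il4r (adjusted p = 0.087). Among annotated groups, genes higher in Hal200 than in control were enriched for axon (85 of 456 genes, 34.7 by chance, adjusted p = 2.0e-11) and antigen processing via MHC class II (10 of 15 genes, 1.14 by chance, adjusted p = 6.5e-06) by Fisher's exact test. Lower genes were enriched for cilium assembly (32 of 193 genes, 9.22 by chance, adjusted p = 2.5e-06). From Hal200 to Hal1000 lower genes were enriched for photoreceptor inner segment (38 of 64 genes, 12.1 by chance, adjusted p = 6.8e-10), and higher ones for GABA-ergic synapse (57 of 106 genes, 18.1 by chance, adjusted p = 6.2e-15). The split into higher and lower genes behind these tests depends on the scaling.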
